A study of Mus musculus with 20 samples.

How the data were processed

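Total RNA was sequenced from 20 mouse tumour tissues: 6 primary sarcomas, numbered 1 to 6, and 14 lung metastases, each matched by its label with 1 of the primary tumours. A primary tumour and its metastases are called a matched set here. Sets 1 and 2 held 4 metastases each, sets 3 and 6 held 2 each, and sets 4 and 5 held 1 each. Metastasis 2-3 is the metastasis numbered 3 of set 2, and 5-x is the unnumbered metastasis of set 5. The genotype label says only that the animals had a mixed background, and no label gives sex, tumour site or time of collection.

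Per the labels' protocols, RNA was extracted with a Direct-zol kit and made into stranded libraries with Ribo-Zero Gold, which depletes ribosomal RNA. Per the submitters' processing notes, Trimmomatic 0.36, STAR (given with the version string 5.5.4b, which is doubtful as a STAR release) and HTSeq were used with the mm10 build. The authors deposited 1 table of whole-number read counts per gene with no normalization, 51826 genes by 20 libraries, and those counts were the start of all work. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies (such as the paired haemoglobin genes and the histones) may be split in ways that cannot be told. Versioned gene identifiers were matched to symbols and to mm10 (GRCm38) coordinates in a GENCODE annotation: 51633 identifiers had a symbol, 47648 of them in the same version, and the 193 without one held 0.017% of the counts.

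Total counts ran from 20603620 to 36824370 per library. No columns were identical. The closest libraries, metastases 6-1 and 6-2 (Pearson r 0.994 across genes), differed by far more than sampling noise, with a chi-square of 29.3 per degree of freedom over 17484 genes. Each library was kept as a sample, as labelled, but this value cannot tell separate metastases from separate libraries of the same tumour.

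Lung metastases were compared with primary tumours by edgeR 4.0.16 in R 4.3.3: genes with low counts were left out with filterByExpr (minimum count 10), libraries were scaled by TMM factors, and a robust quasi-likelihood test was run with the matched set as a block, which left 18452 genes and 13 residual degrees of freedom. The pairing comes from the design text and the titles, which match each metastasis with a primary tumour. As a check, the deviations of primary tumours and of their own metastases from their group means had a mean correlation of 0.0577 over the 1000 most variable genes. Adjusted p is Benjamini-Hochberg adjusted throughout, with a threshold of 0.05. Metastases of 1 set may share an animal, and the block does not remove correlation among them, so sums of each set's metastases were tried as an alternative. CPM were computed from the deposited counts with library totals scaled by the TMM factors, and log2 CPM used a prior count of 2.

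Before the data were examined, 37 gene lists with 1214 symbols were fixed, of which 1212 symbols were found. Each list was tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with the p adjusted over the 37 lists, and again with an estimated correlation and with fry. The mean log2 CPM of a list in a library is called its index. Differences of Neat1 and of each index over the 6 sets were tested with an exact two-sided sign-flip permutation test over 64 sign patterns, whose smallest possible p is 0.03125. Differences between sets were tested among the 12 metastases of sets 1, 2, 3 and 6 with edgeR. Variation of the difference between sets was tested as an interaction, in which the single primary tumour of each set gives no spread of its own. Matching of profiles was set against all 720 assignments of primary tumours to sets (exact permutation, one-sided).

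Genes were named by a rule fixed before the data were examined: Neat1, Malat1, Khsrp, Sfpq, Nono and Pspc1 whatever their result, then, among genes past the threshold with a mean log2 CPM of at least 2 and the same direction in all 6 sets, the 8 largest rises and falls and the 8 rises and falls of smallest p outside the lists of tissues and of blood and immune cells (the antigen presentation and interferon lists are not among those left out), and last the 3 tested members of smallest p in each list, whether past the threshold or not. Gene models with provisional symbols were left out of the middle parts. For genes with 3 or fewer counts in a whole group, the ratio of CPM over the group is given with an exact 95% interval that covers counting error only. Some genes that the rule names are not reported here. A gene named outside the rule is said to have been chosen after its values were seen.

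The scripts were tested on simulated counts. In the comparison of metastases with primary tumours (18274 genes), 0%, 18%, 52% and 84% of 50 genes changed 1.5-fold, 2-fold, 4-fold and 8-fold were recovered, 1 of 78 calls was false, and 0 genes were called with no change. For differences between sets among metastases (18405 genes), 77 of 200 genes changed 4-fold in 1 set were recovered with 2 other genes. For the interaction (18295 genes), 63 of 200 genes raised 32-fold in the metastases of 1 set were recovered with 3 others. Smaller changes were often not detectable with this number of tumours. Apart from the planted changes the simulated libraries varied independently, with no correlation among metastases of a set and no mixing of tissues. The rates of false calls therefore need not hold for the real libraries.

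Alternatives covered the block, sums of each set's metastases, metastasis 1 of each set alone, limma voom, DESeq2 1.42.0, other scaling factors and filters, covariates for lung and muscle content, a test against a 1.5-fold change, and leaving out each set. Splicing itself was not measured, since the counts are per gene.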

Results

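RNA was measured by sequencing in 6 primary mouse sarcomas and 14 lung metastases matched with them, at 20603620 to 36824370 counts per library. The study's title concerns the long non-coding RNA Neat1, metastasis of sarcoma and RNA splicing. The comparisons implied by the design are therefore lung metastases against their primary tumours, with Neat1 and the splicing genes first, and the metastases of different primary tumours against each other. No label says which samples came from separate animals, so p-values measure the spread between these samples.

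Lung metastases differed from their primary tumours in 1354 genes that rose and 1189 that fell, of 18452 tested (edgeR, adjusted p under 0.05, matched set as a block). Of these, 1151 rose and 610 fell by at least 2-fold, and 1126 of the rises and 696 of the falls had the same direction in all 6 sets. Among genes past the threshold with a mean log2 CPM of at least 2 and the same direction in all 6 sets, those of smallest p outside the lists of tissues and of blood and immune cells were Fkbp5, which encodes a co-chaperone of steroid receptors (log2 fold change 1.90 ± 0.161 SE, adjusted p = 4.51e-05, 73.1 ± 26.4 CPM SD in 6 primary tumours and 286 ± 61.4 in 14 metastases), and Col1a2, a chain of type I collagen (-1.77 ± 0.158, adjusted p = 4.85e-05, 3606 ± 1101 and 1121 ± 261 CPM). Fkbp5 lies on chromosome 17 from 28399094 to 28517527 and Col1a2 on chromosome 6 from 4504814 to 4541544. The chloride channel gene Ano1 (2.31), Gdpd2 (3.83), the basement membrane collagen gene Col4a3 (5.62), Aox1 (1.52), Sorcs2 (2.25), Tspan8 (3.63) and Csad (1.48) also rose. Chn1 (-2.25), Riox2 (-1.41), the proline synthesis gene Pycr1 (-1.84), Adgra2 (-2.72), the antigen presentation gene B2m (-1.54), Col5a2 (-1.64) and Atp10a (-2.49) fell. All 16 of these genes moved the same way in 6 of 6 sets. By the same filter on expression and direction, the largest rises were of Scgb1a1 (8.98), Sec14l3 (8.72), Sftpb (7.57), Sftpa1 (7.38), Sftpd (7.26), Sftpc (7.24), Slc34a2 (7.21) and Dnah5 (7.06), which include the secretory protein of airway club cells and all 4 surfactant protein genes. By that filter the largest falls were of Fez1 (-4.49), Col11a1 (-3.65), Crabp1 (-3.32), Esm1 (-2.97), Cxcl10 (-2.92), Masp1 (-2.81), Cavin2 (-2.80) and Oasl1 (-2.77). With the metastases of each set summed, 297 genes rose and 63 fell, and with metastasis 1 of each set alone 307 rose and 108 fell. DESeq2 gave 2310 and 1861, the muscle index as a covariate 2769 and 2130, the T and natural killer cell index as a covariate 2894 and 1894, and a test against a 1.5-fold change 680 and 270. With the lung epithelium index as a covariate 966 rose and 735 fell, but only 459 and 382 of these were shared with the fit without it. With both tissue indices 2197 rose and 1351 fell, with 712 and 622 shared. The fits with a T and natural killer cell index or without sets 4 and 6 were chosen after seeing the data. Without set 1, 567 rose and 432 fell, without set 2, 682 and 407, without set 6, 772 and 596, and with sets 4 and 6 both left out, 785 and 1065.

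Neat1, the RNA that scaffolds paraspeckles, was higher in lung metastases, at 2219 ± 1358 CPM (SD, n = 14) against 797 ± 493 CPM (SD, n = 6) in primary tumours. Neat1 (ENSMUSG00000092274.2) lies on chromosome 19 of mm10 from 5824708 to 5845478, on the minus strand, and is annotated as a lincRNA. Its log2 fold change was 1.55 ± 0.428 (SE), or 2.93-fold, with an edgeR adjusted p of 0.0251. Neat1 was higher in 5 of 6 sets, with differences of 1.89, 1.64, 3.77, 0.63 and 1.59 on the log2 scale in sets 1, 2, 3, 5 and 6 and of -0.93 in set 4. The mean difference over sets, 1.43 ± 1.55 (SD, n = 6), did not pass the exact sign-flip permutation test (p = 0.09375, where 0.03125 is the smallest possible). Malat1, the neighbouring nuclear long non-coding RNA, had a log2 fold change of -0.14 ± 0.338 (adjusted p = 0.821), and values for the RNA-binding protein gene Khsrp (0.14 ± 0.194, adjusted p = 0.683) and the paraspeckle protein genes Sfpq (0.09 ± 0.166, 0.773), Nono (-0.15 ± 0.186, 0.635) and Pspc1 (0.15 ± 0.226, 0.717) did not pass either. The Neat1 call ended with summed metastases (1.48, adjusted p = 0.21), metastasis 1 of each set alone (1.34, 0.212) and a test against a 1.5-fold change (0.0924). It also ended without set 1 (1.39, 0.114), set 2 (1.52, 0.118) or set 6 (1.54, 0.0853), and over all alternatives the adjusted p ran from 0.000342 to 0.212.

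**Figure D1:**
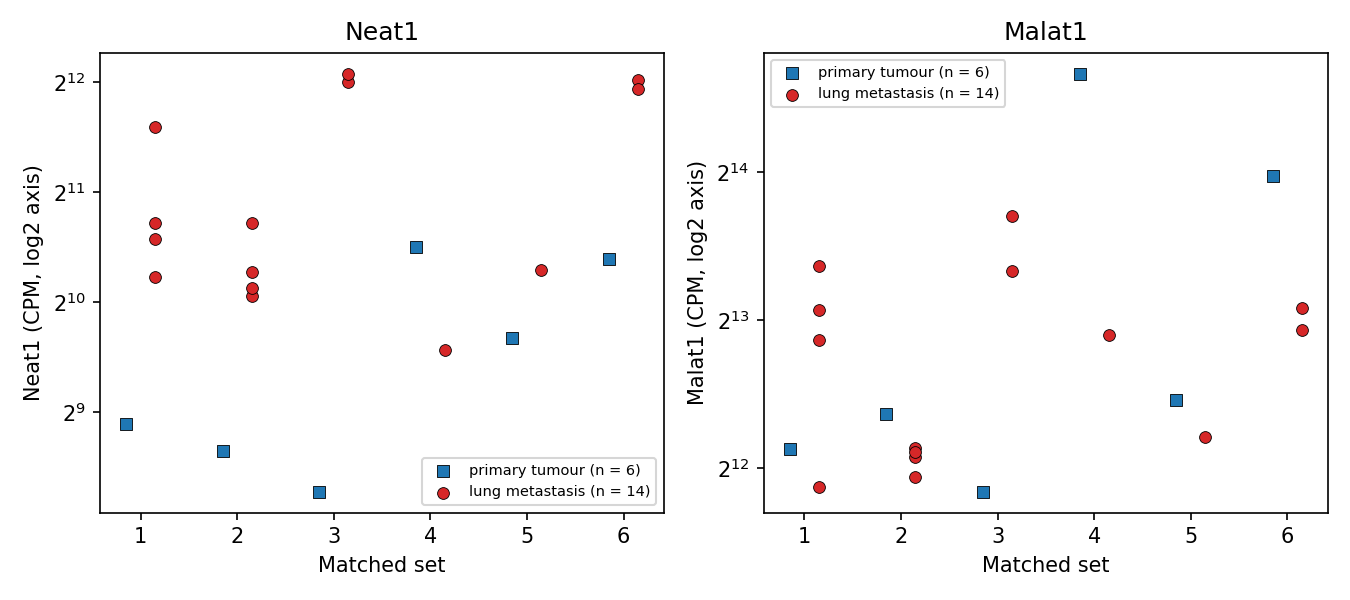
Neat1 (left) and Malat1 (right) in CPM on log2 axes, by matched set, with 1 point per library: squares are the 6 primary tumours and circles the 14 lung metastases. Neat1 is above the set's primary tumour in the metastases of 5 sets and below it in set 4 (755 against 1443 CPM).

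The splicing lists did not pass the list test against other genes. Of 78 tested splicing regulators 4 rose and 8 fell, and the same numbers were found adjusted over the list alone. The risers were the epithelial splicing regulators Esrp1 (6.09 ± 1.18 SE, 0.0851 CPM in primary tumours and 5.40 in metastases) and Esrp2 (4.90 ± 0.756), Pcbp2 (1.22 ± 0.230, 251 and 561 CPM) and Ptbp2 (1.47). Among those that fell were the neuronal regulator Nova1 (-2.60) and the muscleblind genes Mbnl1 (-0.86) and Mbnl2 (-0.57). Ptbp2, Nova1, Mbnl1 and Mbnl2 were chosen after their values were seen. Esrp1 and Esrp2 rose in the metastases together with the lung epithelium list. The splicing regulator list had a median of -0.07 and a mean of 0.04, opposite in sign, and camera gave an adjusted p of 0.22. The mixed test of fry asks whether members change in either direction, without comparing them with other genes, and gave 0.0011. It is not particular to splicing regulators: 15 of the 37 lists passed it without passing camera, such as the p53 targets (1.11e-06). Over all 18452 genes tested, 1354 rose and 1189 fell. Of 70 genes of the spliceosome core, Cdc40 rose (0.55 ± 0.157) and Snrpa1 fell (-0.52 ± 0.131), while Eftud2 (0.42, adjusted p = 0.087) did not pass. Adjusted over the list alone 0 rose and 0 fell by edgeR, with 5 higher and 2 lower at an unadjusted p under 0.05, 2 and 1 by DESeq2 and 1 and 1 by limma voom over all genes (camera adjusted p = 0.539). Of 27 paraspeckle components Neat1 alone rose by edgeR, with 0 adjusted over the list alone, 2 higher and 3 lower at an unadjusted p under 0.05, 2 and 1 by DESeq2 and 1 and 0 by limma voom. The paraspeckle median of -0.06 and mean of 0.02 were opposite in sign, and the camera adjusted p was 0.831. The next members were Zc3h6 (1.11, adjusted p = 0.0772) and Hnrnph3 (-0.75, 0.0994). Without the block, camera placed the splicing regulators lower (median -0.29, adjusted p = 0.0476), as it did without set 3 (-0.17, 0.00805). With sets 4 and 6 left out, the paraspeckle list turned to a median of 0.21 (adjusted p = 0.0211).

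Markers of the surrounding lung were higher in metastases. Of 37 alveolar and airway epithelium genes 26 rose and 1 fell (29 and 1 adjusted over the list alone), with a median log2 fold change of 5.20. They include the lung epithelial transcription factor gene Nkx2-1 (1 count in the primary tumours and 1799 in the metastases, a ratio of CPM of 789 with a 95% counting interval of 141 to 31200), Foxa2 (6.39 ± 1.07) and the keratin gene Krt8 (5.20 ± 0.888, 34.3 and 639 CPM), and the gene that fell was Etv5 (-0.53). The camera adjusted p was 2.7e-11, and 0.668 with an estimated correlation. The epithelial index rose in 6 of 6 sets, by 4.16 ± 1.54 (SD, exact sign-flip permutation p = 0.03125, the smallest possible, and 0.289 adjusted over the 37 lists). In metastases 2-3 and 2-4 it was 1.45 and 0.83, within the range of the primary tumours, of which the highest had 1.60. Of 26 lung endothelium and stroma genes 4 rose, Tcf21 (1 count and 476 counts, ratio 209, interval 37.3 to 8260), Inmt (5.29), Car4 (4.53) and Fmo2 (4.19), and 4 adjusted over the list alone (camera adjusted p = 0.000772, and 0.941 with an estimated correlation). With the lung epithelium index as a covariate the median of the lung endothelium and stroma list turned to -0.61 and Car4 to -0.30, and without sets 4 and 6 the list did not pass camera (0.42). Of 9 skin epithelium genes Dsp (5.52), Perp (3.56) and Col17a1 (2.61) rose, and 4 adjusted over the list alone (camera adjusted p = 0.0303, and 0.668 with an estimated correlation). Fmo2 was chosen after its values were seen.

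Skeletal muscle genes were lower in the metastases of sets 1, 2, 3 and 5. Of 41 tested, 0 rose and 14 fell (0 and 23 adjusted over the list alone), with a median of -3.64, among them Pvalb (-7.39 ± 1.05), Tmod4 (-4.07 ± 0.536) and Myoz1 (-4.39 ± 0.890). The camera adjusted p was 4.59e-14, and 0.668 with an estimated correlation. The median of the skeletal muscle list was -1.41 without set 1, -2.23 with summed metastases, -2.24 with metastasis 1 of each set alone, -2.38 with the lung epithelium index as a covariate and -1.70 with the T and natural killer cell index, and camera passed in each. The muscle index moved the other way in sets 4 and 6, by 1.31 and 4.53, and its mean difference of -2.09 ± 4.19 (SD, n = 6) did not pass the exact sign-flip permutation test (p = 0.25). Primary tumours 4 and 6 had muscle indices of -0.74 and -2.34, while the others had 6.77 to 8.04. Of the 17 myogenic progenitor genes Musk rose (1.62) and Mef2c fell (-1.30), also adjusted over the list alone, and Vgll2 (-2.39, adjusted p = 0.198) did not pass, with a camera adjusted p of 0.476 and a test in the opposite direction to the median of -0.15. Of 15 adipocyte genes Ucp1 fell (-3.42), and 1 adjusted over the list alone, while Car3 (-3.08, adjusted p = 0.0597) and Plin4 (-1.48, 0.101) did not pass (camera adjusted p = 0.115).

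**Figure D2:**
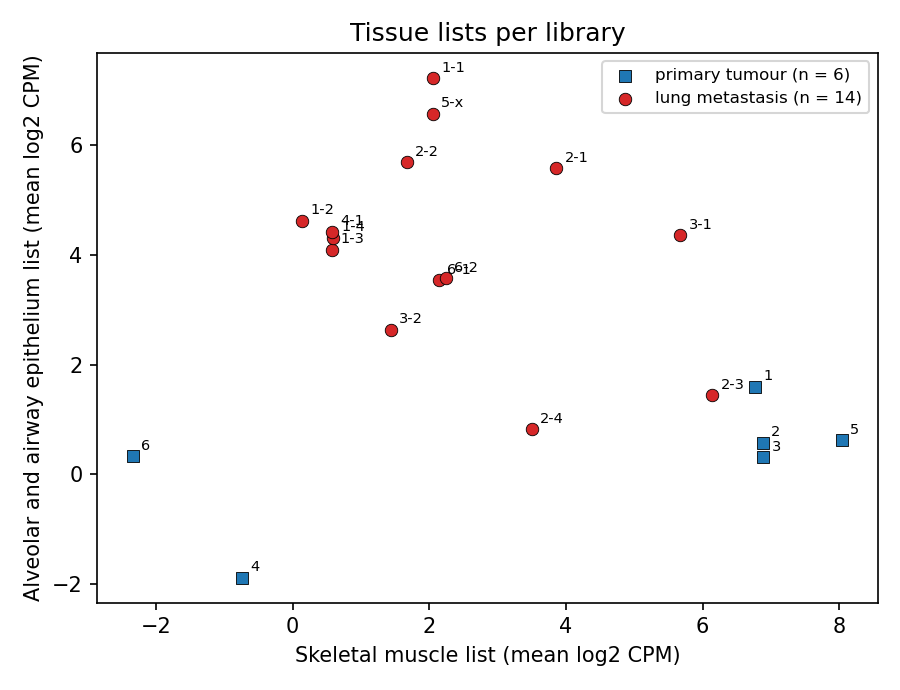
Mean log2 CPM of the skeletal muscle list (horizontal) against the alveolar and airway epithelium list (vertical), 1 point per library: squares are the 6 primary tumours and circles the 14 lung metastases, labelled by number. Primary tumours 4 and 6 lie at muscle values of -0.74 and -2.34, and metastases 2-3 and 2-4 at epithelial values of 1.45 and 0.83.

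Interferon-stimulated genes were lower in metastases: of 41 tested 0 rose and 25 fell (0 and 33 adjusted over the list alone), with a median of -1.77. Rtp4 (-2.38 ± 0.425) and the GTPase gene Irgm1 (-1.96 ± 0.362) were among those of smallest p, and Isg15 (-2.77) and Irf7 (-3.22), chosen after their values were seen, fell too. The camera adjusted p was 2.34e-19, and 0.668 with an estimated correlation. The interferon index was lower in 5 of 6 sets and higher by 1.10 in set 6, with a mean difference of -1.74 ± 1.49 (SD, n = 6, exact sign-flip permutation p = 0.0625). Of 20 antigen presentation genes 0 rose and 6 fell (0 and 7 adjusted over the list alone), including the class I light chain gene B2m (-1.54 ± 0.184, 1068 and 354 CPM), its regulator Nlrc5 (-2.11 ± 0.393) and Erap1 (-0.71 ± 0.171) (camera adjusted p = 4.37e-05, and 0.786 with an estimated correlation). The antigen presentation index was lower in 4 of 6 sets and higher by 2.15 and 2.02 in sets 4 and 6. Its mean difference was -0.35 ± 1.94 (SD, n = 6, exact sign-flip permutation p = 0.6562). The antigen presentation list did not pass with the muscle index (-0.36) or the T and natural killer cell index (-0.32) as a covariate.

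Immune and blood cell markers went both ways. Of 34 T and natural killer cell genes 0 rose and 8 fell (0 and 9 adjusted over the list alone), among them Ccl5 (-2.69 ± 0.331), Lck (-2.04 ± 0.381) and the granzyme gene Gzmb (-4.85 ± 1.10) (camera adjusted p = 9e-05, and 0.941 with an estimated correlation). The mast cell protease genes Cma1 (-4.93), Mcpt4 (-4.67), Tpsb2 (-4.77) and Cpa3 (-5.16, chosen after its values were seen) were the 4 that fell of 19 dendritic and mast cell genes, with 6 adjusted over the list alone (camera adjusted p = 0.00807, and 0.941 with an estimated correlation). In sets 4 and 6 the indices of both lists were higher in the metastases. With the muscle index as a covariate the T and natural killer cell list (0.36) and the dendritic and mast cell list (0.57) did not pass. Of 21 neutrophil genes 8 rose and 0 fell (12 and 0 adjusted over the list alone), with S100a8 (3.91 ± 0.842), Retnlg (4.25 ± 1.03) and Ltf (5.96 ± 1.48) first (camera adjusted p = 9.56e-06, and 0.668 with an estimated correlation), and with the lung epithelium index as a covariate the neutrophil list did not pass (0.36). Of 11 erythroid genes 9 rose and 0 fell (10 and 0 adjusted over the list alone), among them Slc4a1 (5.18) and Epb42 (4.14) (camera adjusted p = 3.24e-07, and 0.668 with an estimated correlation). Of 35 macrophage genes 4 rose, Marco (5.99 ± 0.894), Chil3 (5.92), Mertk (0.98) and Arg1 (3.20), with 4 adjusted over the list alone, a median of -0.28 and a mean of 0.27, opposite in sign, and a camera adjusted p of 0.807 in the direction of the mean. Marco and Chil3 are abundant in alveolar macrophages. Arg1 was chosen after its values were seen. Of 22 B and plasma cell genes 0 passed by edgeR, also adjusted over the list alone, with 6 higher and 1 lower at an unadjusted p under 0.05, 6 and 0 by DESeq2 and 1 and 0 by limma voom (camera adjusted p = 0.147). Blk (2.25, adjusted p = 0.0515) and Ighd (2.23, 0.0858) were among those of smallest p. Of 20 smooth muscle and pericyte genes 0 passed by edgeR, also adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05, 1 and 2 by DESeq2 and 0 and 1 by limma voom. Pdgfrb (-0.95, adjusted p = 0.0843), Tagln (-2.30, 0.191) and Actg2 (1.76, 0.237) had the smallest p, and the camera test (0.675) pointed down where the median of 0.15 was positive. Of 28 endothelial genes Angpt2 rose (1.76) and Esm1 fell (-2.97), the same adjusted over the list alone, and Apln (-1.38, adjusted p = 0.0984) did not pass (camera adjusted p = 0.231). Of 36 chemokine and cytokine genes Cxcl10 (-2.92), Ccl5, Csf1 (-2.28) and Ccl8 (-3.16, chosen after its values were seen) fell, with 2 higher and 5 lower adjusted over the list alone (0.0721).

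**Figure D3:**
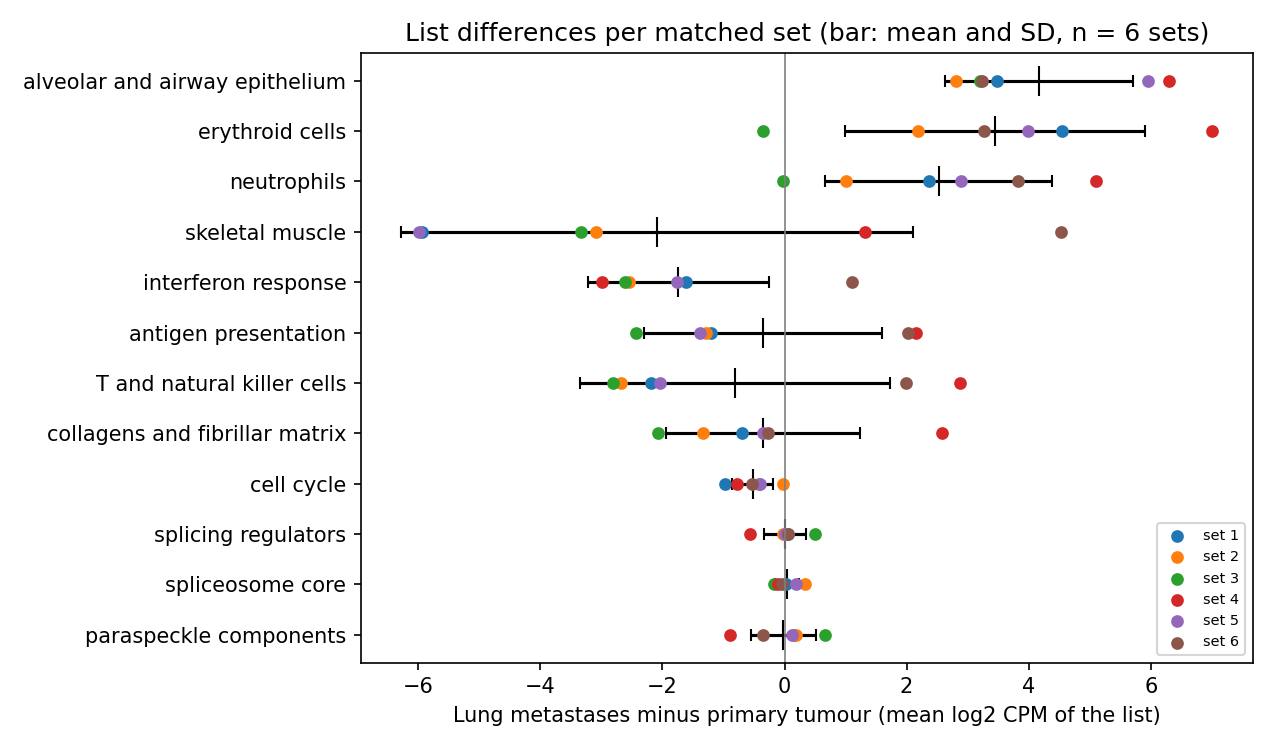
Difference in mean log2 CPM of 12 gene lists between the lung metastases and the primary tumour of each of 6 matched sets, 1 point per set, with a vertical tick at the mean and a bar of 1 SD to each side. The epithelial list is above 0 in 6 of 6 sets and the cell cycle list below 0 in 6 of 6, while sets 4 and 6 lie on the other side of 0 from the rest for skeletal muscle.

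Some matrix and proliferation genes were lower. Of 50 collagen and fibrillar matrix genes 4 rose and 11 fell (4 and 12 adjusted over the list alone), with a median of -0.73. Col1a2 (-1.77 ± 0.158), Col5a2 (-1.64 ± 0.200, 1136 and 388 CPM) and tenascin C, Tnc (-1.75 ± 0.230, 763 and 239 CPM), fell in 6 of 6 sets, while Col18a1 (2.67), Eln (3.20), Thbs2 (1.33) and Vcan (1.19), chosen after their values were seen, rose. The camera adjusted p was 7.76e-05, and 0.923 with an estimated correlation. The collagen index was lower in 5 of 6 sets and higher by 2.58 in set 4, with a mean difference of -0.36 ± 1.59 (SD, n = 6, exact sign-flip permutation p = 0.5938). Of 52 cell cycle genes 0 rose and 10 fell (1 and 16 adjusted over the list alone), with a median of -0.56. Cdc6 (-0.85 ± 0.213), Cdc45 (-0.68 ± 0.179) and Ttk (-0.89 ± 0.244) had the smallest p, and the proliferation markers Mki67 (-1.17) and Top2a (-0.97), chosen after their values were seen, fell as well (camera adjusted p = 7.67e-09, and 0.758 with an estimated correlation). The cell cycle index was lower in 6 of 6 sets, by -0.52 ± 0.331 (SD, exact sign-flip permutation p = 0.03125, the smallest possible, and 0.289 adjusted over the 37 lists). With the lung epithelium index as a covariate the median of the cell cycle list was 0.05 and did not pass. Of 31 replication-dependent histone genes 0 passed by edgeR, also adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 and 0 by DESeq2 and by limma voom. Their median was -0.59 (camera adjusted p = 0.00167, and 0.941 with an estimated correlation), with Hist1h2ab (-1.33, adjusted p = 0.16), Hist1h1e (-0.82, 0.228) and Hist1h3b (-0.97, 0.256) first. The histone median turned to 0.90 with the lung epithelium index as a covariate and to 1.09 with both tissue indices. The histone index (-0.83 ± 0.666 SD) was lower and the skin epithelium index (1.96 ± 0.607 SD) higher in 6 of 6 sets, each with the same exact permutation p. Of 30 mesenchymal transition genes Sdc1 (1.39 ± 0.243), Tgfb2 (0.94) and Cdh2 (0.51) rose and 6 fell, including Twist2 (-2.20 ± 0.337) and Snai2 (-1.61 ± 0.292), with 3 and 7 adjusted over the list alone (0.147). Of 44 matrix protease genes 5 rose and 5 fell. Plat (1.28 ± 0.272), Timp3 (2.10), Mmp8 (3.34) and Mmp12 (3.52) were among those that rose, and Adam19 (-1.20 ± 0.215), Mmp16 (-0.99), Adam17 (-0.73), Adam9 (-0.49) and Ctsk (-2.83) fell, with 7 and 6 adjusted over the list alone (0.621). Tgfb2, Cdh2 and the last 3 of the rising and last 4 of the falling protease genes were chosen after their values were seen.

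Among developmental and signalling lists, genes of the Wnt pathway and of body position moved in both directions. The Wnt target and feedback genes Notum (4.10 ± 0.822), Nkd1 (3.78), Lgr5 (2.65) and Tcf7 (1.71) rose and Ror2 (-3.42 ± 0.689), Dkk2 (-2.75 ± 0.409, 684 and 124 CPM) and Sfrp4 (5.22 and 1.23 CPM) fell, of 31 tested (4 and 3 adjusted over the list alone, camera adjusted p = 0.291). Of 20 Hox and limb position genes Tbx5 (5.83), Tbx4 (3.86) and Hoxc9 (1.01) rose and Pitx1 (-6.51 ± 0.932), Hoxd8 (-3.31 ± 0.485), Hoxd9 (-2.78), Tbx15 (-2.17 ± 0.385) and Emx2 (-2.15) fell, with 5 and 6 adjusted over the list alone, a median of 0.06 and a mean of -0.19, opposite in sign, and a camera adjusted p of 0.75 in the direction of the mean. Pitx1 is a hindlimb factor, and Tbx4 and Tbx5 are also lung mesenchyme factors. Of 14 cardiac genes Nppa (3 counts and 1837 counts, ratio of CPM 268, 95% counting interval 91.7 to 1300), Myl7 (2 counts and 1141 counts, ratio 250, 69.1 to 2070), Tbx5 and Ryr2 (4.26) rose and Myl2 (-4.28) fell, with 5 and 2 adjusted over the list alone (0.444). Nppa was at 30.3 CPM in metastasis 4-1 and 14.7 in 3-1, and at 0 to 5.63 CPM in the other metastases. Of 16 nerve genes 1 rose, Mal (2.92), and 2 fell, among them Cdh19 (-4.41), with 2 and 2 adjusted over the list alone (0.807). Nkd1, Lgr5, Tcf7, Sfrp4, Tbx4, Hoxc9, Hoxd9, Emx2, Nppa and Ryr2 were chosen after their values were seen.

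None of the remaining lists passed camera in the comparison as first given. Without sets 4 and 6 the hypoxia and glycolysis list turned to a median of 0.47 and passed. Of 39 long non-coding RNAs Neat1 and Snhg11 (3.35), which the annotation used here types as protein-coding, rose and Dleu2 (-1.02) fell, the same adjusted over the list alone (camera adjusted p = 0.621). Of 35 hypoxia and glycolysis genes Aldoc (2.49) and the lactate transporter gene Slc16a3 (1.85) rose and P4ha1 (-1.32) and Aldoa (-1.24, chosen after its values were seen) fell, the same adjusted over the list alone (0.807). Of 22 genes of MAPK output Spred2 rose (0.55) and Etv5 fell (-0.53), the same adjusted over the list alone, and Etv4 (0.70, adjusted p = 0.127) did not pass (camera adjusted p = 0.357). Of 23 p53 targets Perp (3.56) rose and Ccng1 (-0.88) and Plk2 (-1.57) fell, with 2 and 5 adjusted over the list alone, a median of -0.09 opposite in sign to the mean, and a camera adjusted p of 0.535. Of 29 early response genes Jun (-0.81) and Hsph1 (-0.70) fell, 2 adjusted over the list alone, and Hmox1 (0.97, adjusted p = 0.191) did not pass (0.675). Of 67 ribosomal protein genes Rpl13a (-0.99) and Rpl15 (106 and 32.9 CPM) fell and Rpl31 (-0.69, adjusted p = 0.0796) did not pass. Adjusted over the list alone 0 ribosomal genes passed by edgeR, with 2 higher and 8 lower at an unadjusted p under 0.05, 1 and 3 by DESeq2 and 0 and 3 by limma voom (camera adjusted p = 0.214). Of 46 oxidative phosphorylation genes Ndufb9 rose (0.65) and Sdha fell (-0.47), the same adjusted over the list alone, and Uqcrc2 (-0.54, adjusted p = 0.0519) did not pass. The camera test (0.978) pointed down where the median of 0.05 was positive. Of 7 mitochondrially encoded genes 0 passed by edgeR, also adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05 and 1 and 0 each by DESeq2 and limma voom. mt-Nd5 (0.82, adjusted p = 0.105), mt-Nd1 (0.53, 0.299) and mt-Nd4 (0.43, 0.349) had the smallest p (camera adjusted p = 0.147).

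Among the 12 metastases of sets 1, 2, 3 and 6, 64 of 19919 genes differed between sets (edgeR, 5870 at an unadjusted p under 0.05). By annotation 36 of the 64 were provisional transcript models (TEC) and 16 were protein-coding. The macrophage gene Arg1 had mean log2 CPM of 7.72 and 7.23 in sets 1 and 2 and of 2.61 and 2.30 in sets 3 and 6. The antisense RNA Kcnq1ot1 had 5.57, 5.07, 7.62 and 7.25 in the same order. Both were chosen after their values were seen, and both have an adjusted p of 0.0475. The mean log2 CPM of 1237 transcripts annotated as TEC or sense intronic is called the unspliced RNA index here. Unspliced RNA was not measured itself. The index moved with these sets, at 0.49 to 1.11 in the metastases of sets 3 and 6 and -0.88 to 0.20 in those of sets 1 and 2. It is not separate evidence, since 36 TEC and 2 sense intronic models of the same types are among the 64 genes. Leaving out set 1, 2, 3 or 6 gave 0, 2346, 1 (the pseudogene Rpl14-ps1) and 0 genes by edgeR, with 2971, 6117, 5906 and 4688 at an unadjusted p under 0.05, so the count rests on which sets enter. With all 4 sets limma voom gave 511 genes. Over all 14 metastases, pairs of the same set had a mean correlation of 0.297 (14 pairs) against -0.125 for other pairs (77 pairs), across genes, which are not independent replicates, with a permutation p of 0.017. This mean does not describe each set. Pairs of set 1 had 0.32 to 0.87, 3-1 with 3-2 had 0.23 and 6-1 with 6-2 had 0.96. In set 2, 2-1 with 2-2 had 0.79 and 2-3 with 2-4 had 0.77, but pairs across these had -0.41 to -0.70. Metastasis 2-2 had 0.89 with 5-x of another set.

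Matching of primary tumours with their own metastases depended on the genes used. The mean correlation between a primary tumour's deviations and those of its own metastases was 0.0577 across the 1000 most variable genes, where the best of the 720 assignments gave 0.149 (exact permutation p = 0.169, one-sided). Of 14 metastases, 6 were closest to their own primary tumour, and 4 of these were the metastases of set 1, with 4-1 and 6-1 the others. In sets 2, 3 and 5, 0 were. Over all tested genes the mean correlation was 0.177 (exact permutation p = 0.0361). The difference between metastases and primary tumour varied between sets in 756 of 18452 genes (edgeR interaction test, 4096 at an unadjusted p under 0.05), and with sets 4 and 6 left out in 0 (1028 at an unadjusted p under 0.05). With all sets limma voom also gave 756 genes. For Neat1 the interaction had an adjusted p of 0.0619.

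**Figure D4:**
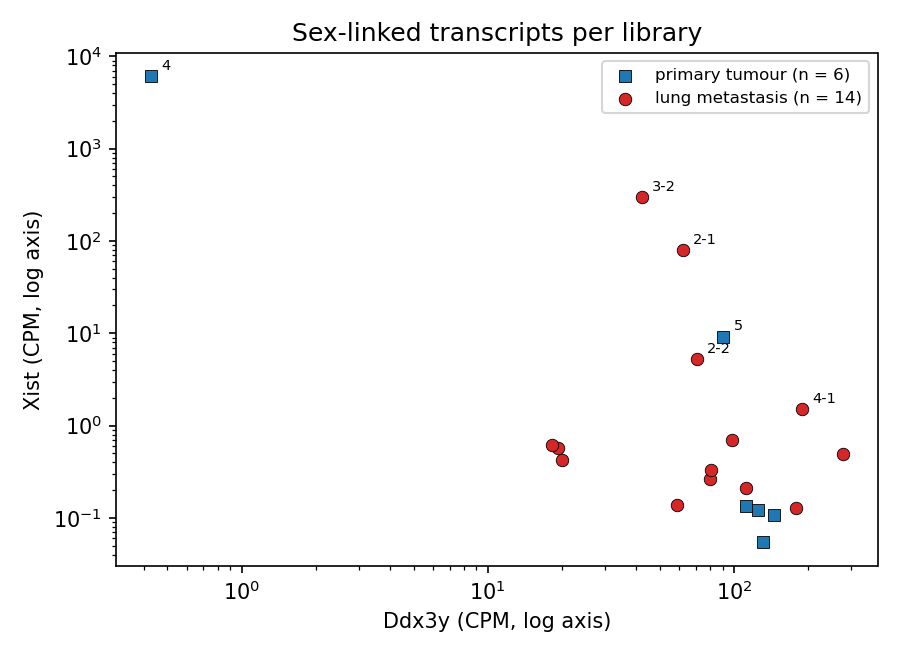
Ddx3y, a gene of the Y chromosome (horizontal), against Xist, the RNA of the inactive X chromosome (vertical), in CPM on log axes, 1 point per library: squares are the 6 primary tumours and circles the 14 lung metastases, with numbers beside libraries above 1 CPM of Xist. Primary tumour 4 has 6070 CPM of Xist and 0.428 CPM of Ddx3y, and its metastasis 4-1 has 1.51 and 189.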

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

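The tests on primary tumours 4 and 6, the Neat1 tests on Malat1, on unspliced RNA and on metastases 2-3 and 2-4, and the fits that leave out sets 4 and 6 or add a T and natural killer cell or unspliced RNA term were chosen only after the result was seen.

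Primary tumours 4 and 6 each lay apart from the other 5 primary tumours in some values, together 13 of 48 examined, where chance sets a library apart in about 1 in 20 groups. Primary tumour 4 had a TMM factor of 0.712 (nearest other 0.979), 6074 CPM of Xist (9.21), 36.3 CPM of Khsrp (95.9), 612 CPM of Sfpq (273) and list means in log2 CPM of 7.44 for splicing regulators (6.65), -1.88 for alveolar and airway epithelium (0.31), 6.05 for mesenchymal transition genes (7.11), 5.06 for oxidative phosphorylation (6.00), 10.73 for mitochondrially encoded genes (8.44) and -0.77 for histones (3.21). Primary tumour 6 had 6.31 for cell cycle genes (5.93), 7.46 for hypoxia and glycolysis (5.92) and 0.76 for interferon response (4.84). Metastases 4-1 and 3-2 stood apart with primary tumour 4 in Khsrp (32.1 and 42.6 CPM), Sfpq (396 and 497 CPM) and the share of counts on Rmrp (0.00307% and 0.0117%, against 0.00172% in primary tumour 4), and 3-2 correlated best with primary tumour 4 (r = 0.435), for a cause that was not tested.

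For the pattern of primary tumours 4 and 6, loss of the Y chromosome in primary tumour 4 is argued against by its Xist level of 6074 CPM, which a male tumour without its Y would lack. Its Ddx3y level of 0.428 CPM, against 189 CPM with 1.51 CPM of Xist in metastasis 4-1, may mean that this pair came from different animals, and a wrong label or an exchange with a sample outside the series stays open. Both tumours were among the lowest 4 of 20 libraries in 15 of 16 tissue and cell type lists, which is consistent with little host tissue in them, as in a cell culture or a very pure piece of tumour. No biological explanation was tested, since no group of the design separates these tumours.

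The difference between metastases and primary tumours varied between sets in 756 genes, and among named genes in Hif3a (interaction adjusted p = 0.0194), Gzmd (0.0298), Cpa3 (0.0487), Tcf7 (0.0215) and Timp3 (0.0236), by edgeR. Of 60 regroupings of the metastases among sets, the real one included, 8 gave as many genes, with 5549 in the highest of the others. The primary tumours stayed in their sets, so differences among them entered every regrouping. The regroupings therefore neither exclude chance nor show it. With sets 4 and 6 left out 0 genes passed by edgeR, with 1028 at an unadjusted p under 0.05.

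Neat1 was higher in metastases, and lung cells and a larger share of nuclear RNA were weighed. With the lung epithelium index as a covariate the log2 fold change was 2.35 ± 0.586 (SE), so it did not shrink. This does not decide on lung epithelial content as a linear trend. Only metastases 2-3 and 2-4 had the index within the range of the primary tumours, and the covariate was not tried without them. They had Neat1 1.85 above primary tumour 2 on the log2 scale. They carry liver transcripts, so lung cells in every metastasis cannot be told apart from other host cells there. The unspliced RNA index as a linear trend is argued against by a log2 fold change of 1.56 ± 0.290 with it as a covariate, though nuclear RNA was not measured itself. Malat1 was at -0.14 with an upper limit of 2 SE of 0.53, below 0.78, which is 0.5 of the Neat1 change. That SE does not allow for correlation among metastases of a set. Over the 6 sets the mean Malat1 difference was -0.16 ± 1.21 (SD), too wide to decide on a mean rise of nuclear RNA. Malat1 differed by -0.30, -1.76, -0.255 and -0.96 in sets 2, 4, 5 and 6. In sets 1 and 3 it rose by 0.665 and 1.675 together with Neat1, so a rise of nuclear RNA stays open there. Neat1 from lung cells, epithelial or other, and the biological difference between lung and primary site, stay open.

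Interferon response genes were lower in metastases, with a median log2 fold change of -1.77. With both the lung and muscle indices as covariates the median was -2.10, so it did not shrink. Only metastases 2-3 and 2-4 had a lung index within the range of the primary tumours. The fit therefore does not decide on the lung share as a linear trend. Primary tumour 4 alone is argued against (-1.57 without set 4). With the T and natural killer cell index as a covariate the median was -1.48, but this cannot set aside fewer of these cells. In sets 1, 2, 3, 5 and 6 the interferon index and the T and natural killer cell index moved the same way. They parted only in set 4 (-2.98 and 2.88), whose pair may come from different animals. The covariate was not tried without set 4. Other differences between the lung and the primary site may contribute and were not tested.

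For the 2543 genes that changed between metastases and primary tumours, 100 choices of 1 library per set as the primary tumour were drawn from 900 possible. Only the real choice gave as many genes. This argues against chance for the count, not for each gene. It is a weak comparison: 95 other choices gave no gene, and each of these counted more than 1 real primary tumour as a metastasis. The highest other choice gave 1553, with metastasis 3-2 in place of primary tumour 3 and the other 5 primary tumours in their own places. With metastasis 2-3 alone in place of its primary tumour the count was 349. For the 64 genes that differed between sets among metastases chance could not be excluded, since 9 of 100 regroupings, the real one included, gave as many, with 2820 in the highest of the others, which points to a structure of the samples other than the sets.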

How the results depend on the processing

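The fits without sets 4 and 6, without metastases 2-3 and 2-4 or other single libraries, and with a T and natural killer cell or unspliced RNA term were chosen after seeing the data. Of 156 genes past the threshold that were followed one by one besides Neat1, 29 stayed past it in each of the 25 alternatives of the gene test in which they were tested. The other 127 were lost in at least 1 (100 no longer reached the threshold with summed metastases, 96 with metastasis 1 alone and 71 with the lung covariate, where others turned in direction). A gene that a filter removed from an alternative was not counted as lost there. Without the block for the pairing, 1221 genes rose and 1263 fell, of which 1062 and 893 were shared with the fit that had it, Neat1 was 1.48 (adjusted p = 0.0336), and the splicing regulators came past the threshold at -0.29. Depth limits the values of genes with few counts in a group, such as Nkx2-1 (1 count in the primary tumours).

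Counts of genes higher and lower moved by over 1.5 times with summed metastases (297 and 63), metastasis 1 of each set alone (307 and 108), DESeq2 (2310 and 1861), the muscle covariate (2769 and 2130), the T and natural killer cell covariate (2894 and 1894) and a test against a 1.5-fold change (680 and 270). The lung covariate gave 735 lower, both tissue covariates 2197 higher, and sets 4 and 6 left out 785 higher and 1065 lower, 42.4% higher against 53.2%. Leaving out 1 set gave 567 to 1643 higher and 407 to 1409 lower. Summing and single metastases leave fewer samples; elsewhere the cause was not tested.

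Neat1 stayed above 0 throughout but lost its call with summed metastases (1.48), metastasis 1 alone (1.34) and the 1.5-fold test (1.55, adjusted p = 0.0924), and without set 1, 2 or 6, with 1.18 to 1.91 over the sets left out. Adjusted p ran from 0.000342 (DESeq2) to 0.212. Splicing regulators passed camera with metastasis 1 alone (-0.17), no filter (-0.11), the muscle covariate (-0.19), the T and natural killer cell covariate (-0.19) and without set 3 (-0.17, adjusted p = 0.00805), and gave -0.17 to 0.03 over the sets left out. For splicing regulators the mixed test of fry passed (median -0.07, adjusted p = 0.0011) where camera did not (0.22). The same held for 15 of the 37 lists, this one included. The spliceosome core passed with the lung covariate (0.27), and the paraspeckle list turned to 0.21 without sets 4 and 6. With an estimated correlation the epithelial (5.20) and muscle (-3.64) lists lost their calls. The covariates are built from these lists, so values of 0.07 and 0.39 (epithelium) and 0.17 and 0.33 (muscle) with their own and with both covariates decide nothing. The epithelial index without sets 4 and 6 was 3.86 (exact p = 0.125, the smallest for 4 sets).

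With the lung covariate the direction turned for genes of its own list, which decides nothing, Sftpb (-0.54), Sftpa1 (-3.02), Sftpd (-1.32), Sftpc (-2.65), Slc34a2 (-0.97), and for Car4 (-0.30), Eln (-1.02), Ryr2 (-0.33) and Hsph1 (0.01) and for the lists of lung endothelium (-0.61), B cells (-1.88), endothelium (-1.44) and histones (0.90). With both covariates it turned for the same genes of that list, Sftpb (-0.97), Sftpa1 (-3.31), Sftpd (-1.86), Sftpc (-3.26), Slc34a2 (-1.45), and for Car4 (-0.14), Retnlg (-0.04) and Hsph1 (0.12) and for B cells (-0.89) and histones (1.09). Hypoxia turned without sets 4 and 6 (0.47), and dendritic and mast cells (0.69) with the T and natural killer cell covariate. The camera direction alone turned, with the median on the same side of 0, for macrophages with the lung covariate (-2.43), with both (-1.03) and without sets 4 and 6 (-1.02), for lung endothelium with both (0.48), for smooth muscle with the T and natural killer cell covariate (1.92), and for oxidative phosphorylation without set 3 (0.17, with -0.04 to 0.17 over the sets left out). The T and natural killer cell list (0.85) is that covariate, so its turn decides nothing. For the others the cause was not tested.

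Genes differing between sets among metastases numbered 157 with a stricter filter, 511 with limma voom, 1106 with the lung covariate, 0 to 2346 over the sets left out (edgeR, 2971 to 6117 at an unadjusted p under 0.05) and 6845 without metastases 2-3, 2-4 and 3-2. Matching gave 0.177 over all tested genes (exact permutation p = 0.0361) and did not pass in any other version tried. The interaction gave 0 genes by edgeR without sets 4 and 6 (1028 at an unadjusted p under 0.05), against 756 by edgeR and by limma voom with all sets.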

Other observations

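The test of glucocorticoid-induced genes and its repeats with the lung epithelium index as a covariate followed from Fkbp5, Tsc22d3 and Per1 having been seen, 1 member of the clock list, Ciart, had been seen as well, and all values of single libraries below were chosen after they were seen.

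Genes induced by glucocorticoids were higher in metastases. Beside Fkbp5 (log2 fold change 1.90), Tsc22d3, also called Gilz (1.54 ± 0.230 SE), the clock gene Per1 (2.85 ± 0.464) and the transcription factor gene Zbtb16 (3.21 ± 0.860) rose. Sgk1 (0.49 ± 0.240, adjusted p = 0.192) and Pdk4 (0.20 ± 0.434, 0.803), also induced by glucocorticoids and seen before the list was written, did not pass and were left out of it. Of 16 other genes listed as induced by glucocorticoids before they were looked at, Hif3a (4.93 ± 0.768), Map3k6 (1.85 ± 0.373), Arrdc2 (1.22 ± 0.285) and Klf9 (1.09 ± 0.348) rose and 0 fell. Their median was 0.96, and the list was higher in 6 of 6 sets (exact sign-flip permutation p = 0.03125, the smallest possible, camera p = 0.000296). Adjusted over the 3 lists tried, the camera p was 0.000889, and with an estimated correlation it was 0.0766, which does not pass 0.05. The lung epithelium index also rose in 6 of 6 sets, and metastasis 1-1, with the highest index (7.23), had the highest Per1 (293 CPM) and Zbtb16 (131 CPM). With the index as a covariate the lowest of Fkbp5, Tsc22d3 and Per1 was 1.61 ± 0.354 (Tsc22d3), and the median of the 16 genes was 0.77 (camera p = 0.0187), with 4 higher (Hif3a, Map3k6, Arrdc2 and Mt2) and 0 lower. Klf9 lost its call (1.42, adjusted p = 0.102), and Glul went from 0.92 to 0.01, Dusp1 from 0.63 to -0.21 and Angptl4 from 0.81 to -1.50. These values do not decide on lung epithelial content as a linear trend for the 3 genes. Only metastases 2-3 and 2-4 had the index within the range of the primary tumours. They carry liver transcripts, and the covariate was not tried without them. The trend is not decided for the list either, where with the covariate no listed gene lay between Nfkbia (0.12) and Klf9 (1.42). The median of 0.77 falls in that gap and stands for neither side. Other lung cells were not tested. A stronger glucocorticoid signal in the lung metastases is a candidate explanation, as a hypothesis that the estimated correlation leaves open. The time of day of collection cannot be told apart from it: a list of 12 clock output genes, of which Tef (0.73), Hlf (1.45) and Per2 (1.24) rose, gave a camera p of 0.163, which neither shows nor excludes a shift of the clock, and collection times are not given.

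The cytokine receptor gene Il1rl1 fell by 5.52 on the log2 scale (edgeR adjusted p = 0.000707) and the granzyme gene Gzmd fell by 8.09 (0.000807). Il1rl1 was at 342, 628, 695, 12, 73.2 and 504 CPM in primary tumours 1 to 6 and at 2.38 to 30.1 CPM in the metastases. It was lower in 5 of 6 sets, and in set 4 metastasis 4-1 had 12.8 CPM. Gzmd was lower in 4 sets: it was at 5.05, 164, 248 and 2.15 CPM in primary tumours 1, 2, 3 and 5, at 0 in primary tumours 4 and 6, and at 0 to 0.562 in the metastases.

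Metastasis 2-3 held liver transcripts, with 7620 CPM of albumin (Alb), 2640 of Apob, 1260 of Apoa1 and 1760 of Ahsg, and metastasis 2-4 held 942 CPM of Alb. In 20 of 20 listed hepatocyte genes 2-3 was the highest and 2-4 the next highest of all libraries, as hepatocyte RNA in both would give. Whether it came from tissue taken with the sample or from the handling of RNA was not tested.

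Metastasis 3-1 held 374 CPM of Krt4 and 347 of Krt13, keratins of stratified epithelium. Metastasis 4-1 held 30.3 CPM of the atrial gene Nppa, 15.3 of Bmp10 and 10.6 of Pln. The tumour suppressor gene Cdkn2a was at 0.16 and 0.841 CPM in primary tumours 4 and 6 and at 3.16 in metastasis 2-3. It was at 30.4 in metastasis 4-1, at 208 and 284 in 6-1 and 6-2, and at 242, 302 and 233 in 2-1, 2-2 and 2-4. Cdkn2b was at 0.0534, 0.336 and 1.31 CPM in primary tumours 4 and 6 and metastasis 2-3, and at 18.2 to 116 in the other libraries. Kdm5d of the Y chromosome was at 0.0336 CPM in primary tumour 6, beside 112 CPM of Ddx3y, and at 7.89 and 6.67 in metastases 6-1 and 6-2. Whether these differences within sets 2, 4 and 6 come from a wrong pairing was not tested. Xist was at 296 and 80.3 CPM in metastases 3-2 and 2-1, beside 42.2 and 62 CPM of Ddx3y.

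The unspliced RNA index, over 1237 TEC and sense intronic transcripts, was 0.91 and 1.11 in metastases 3-1 and 3-2. It was 0.57 and 0.49 in metastases 6-1 and 6-2, and 1.04 in primary tumour 4. Over the 6 sets its mean difference was -0.03, higher in 3 of 6 (exact sign-flip permutation p = 1).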
